A study of Homo sapiens with 9 samples.

How the data were processed

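The samples were 9 arrays of Y79 human retinoblastoma cells on the Affymetrix PrimeView platform, in 3 groups of 3. The groups were untreated cells, cells given bare gold nanoparticles, and cells given gold nanoparticles that carry an HDM2 peptide. Per the labels, biotin-labelled RNA was made from total RNA by the maker's protocol. Dose, time, the culture each array came from and the dates of processing were not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

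The deposited values were on a log scale, taken as log2, relative to a baseline of each probe set, and the tool that summarized the probes was not given in the sources used here. A base of 10 was ruled out by the values. With natural logs 3 probe sets would pass the scanner maximum, so base 2 was used without other proof of it, and fold changes rest on that choice. The baseline was inferred from the values, of which 59.69% of probe sets held an exact 0 on at least 1 array. A median of 15 arrays, 6 more than these 9, would give 60%. The number 15 was picked to match that share, so the match is no separate check. The values therefore carry no absolute level. The step size of the stored numbers left a trace of the level before the baseline was taken away. From it probe sets were put in classes of baseline level 2 to 4 (15568), 4 to 8 (23409) or 8 to 16 (8949), and 1367 were not classed. On simulated numbers the classes were right for 95.1%. The text calls these classes dim, middle and bright.

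Of 49395 probe sets, 102 array controls were left out and 49293 were tested. By the annotation, 44988 probe sets had 1 gene symbol, 1832 had several and 2473 had none, and 18132 genes had at least 1 probe set of their own. A gene was taken as the mean of its single-symbol probe sets. The plan, made before the data were examined, took the probe set of highest mean, which values without a level do not allow. A planned filter on dim probe sets was replaced by the level classes for the same reason. 1 gene of the naming rule below is not reported here.

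Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided moderated tests) and data.table, version 1.17.8. All 9 arrays entered one fit, so that each probe set had 1 estimate of spread. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, or over all genes where a gene is named, at a threshold of 0.05. Errors are standard errors of the log2 difference from the fit unless SD is written. The 3 comparisons were conjugate with untreated, bare particle with untreated, and conjugate with bare particle. The correlation of the 2 changes against the shared untreated arrays was set beside 100 simulated data sets with unchanged groups.

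Gene lists fixed at the same time were tested with camera in limma at its preset correlation of 0.01, adjusted over 30 lists. They were p53 targets, regulators of p53 and HDM2, pro-apoptotic, anti-apoptotic, G1/S and replication, G2/M, DNA repair, metal response, NRF2, heat shock, ATF4 and unfolded protein response, lysosome and autophagy, endocytosis, cholesterol synthesis, NF-kB, interferon, hypoxia and glycolysis, immediate early, MYC and ribosome biogenesis, ribosomal protein, oxidative phosphorylation, retinoblastoma and microRNA processing genes. Markers were of photoreceptors, retinal progenitors, Mueller glia, inner retinal neurons, pigment epithelium, fibroblasts and blood cells. Members past the threshold were counted over all genes and also adjusted over the list alone.

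Genes were named by a fixed rule. It took MDM2, MDM4 and CDKN1A whatever their values, and the 8 largest rises and 8 largest falls among genes past the threshold whose 3 values in one group lay apart from the 3 in the other, which chance gives for 10% of genes. It also took up to 2 rising and 2 falling members of each list with the smallest adjusted p. With bare particles only 4 genes passed, all of them named. Genes of the fit with bare particle and untreated arrays alone, and the gene families picked by symbol, were chosen after their values were seen.

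The fit was tested on simulated data with the spread of these groups. Of added changes of log2 1, 2 and 3, it found 38.8%, 74.6% and 97% for the conjugate against untreated cells, 13.4%, 62.7% and 84.8% for the bare particle against untreated cells and 34.3%, 74.6% and 93.9% for the conjugate against the bare particle. Of the calls made, 355 of 495, 10 of 117 and 231 of 366 were false. The simulated groups kept the unequal spread of the real ones (median SD within a group 0.474 for conjugate, 0.181 for untreated and 0.116 for bare particle arrays), which the fit takes as equal. Counts of calls that involve the conjugate are therefore likely too high, by a share the simulation does not fix.

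Alternatives were quantile normalization, median centring, leaving out each array, the replicate number as a block, a fit of the 2 groups compared, trend and robust settings, array weights, stricter thresholds, an estimated correlation, fry, Spearman correlation and separate untreated arrays. Quantile normalization gives all arrays the same spread of values. Before it the SD over probe sets was 0.241 to 0.361 on untreated, 0.277 to 0.318 on bare particle and 0.645 to 1.485 on conjugate arrays. It therefore widens differences between bare particle and untreated arrays and narrows the conjugate values, so sizes and counts after it are not like those as deposited. Added after the data were seen were centring each array on the median of each level class, leaving out dim probe sets, taking replicate 3 alone for the conjugate or for untreated cells, and the most specific probe set of each gene. Figures were drawn with matplotlib 3.10.9.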

Results

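In Y79 retinoblastoma cells given the HDM2 peptide conjugate, p53 target genes did not rise as a group against untreated cells. MDM2, which codes for HDM2 and is itself induced by p53, changed by log2 -0.35 with a standard error of 0.15 (n = 3 arrays per group; limma adjusted p = 0.0634). MDM4, the related p53 inhibitor, changed by -0.29 with an error of 0.32 (adjusted p = 0.426). The cell cycle inhibitor CDKN1A changed by -0.88 with an error of 0.37 (adjusted p = 0.0611). None of these 3 genes passed the limma threshold of adjusted p under 0.05 as deposited, but after each array was centred within level classes MDM2 passed as lower (-0.49, adjusted p = 0.0176). The same centring turned the direction of the other genes, MDM4 to 0.435 and CDKN1A to 0.186. Of the 11 probe sets of MDM2 that were averaged, 1 rose and 3 fell. CDKN1A lay at 1.46 and 1.04 on untreated replicates 1 and 2 but at -0.11 on untreated replicate 3.

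Of 30 measured p53 target genes, 12 fell and 1 rose with the conjugate, and 17 did not pass. The falls included TIGAR, which restrains glycolysis (-2.12 with an error of 0.29), the stress sensor SESN1 (-1.89 with an error of 0.31) and the apoptosis gene PMAIP1 (-1.76 with an error of 0.45). PHLDA3, an AKT inhibitor, rose by 0.72 with an error of 0.22. Adjusted over the list alone, 10 fell and 1 rose. The list median was -0.66 (camera adjusted p = 1.16e-04; adjusted p = 0.479 with an estimated correlation). Against untreated replicate 3 alone the median was -0.24 and camera made no call (adjusted p = 0.0743). Among 19 regulators of p53 and HDM2, 12 fell and none rose, over all genes and over the list alone (median -0.78, camera adjusted p = 4.56e-05; adjusted p = 0.479 with an estimated correlation). These falls included the transcription factor YY1 (-1.71 with an error of 0.18) and the acetyltransferase CREBBP (-1.42 with an error of 0.24). The median of the regulators stayed at -0.75 after centring within level classes, while CREBBP went to 0.08 in its most specific probe set.

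Genes of mitosis and DNA replication held 4 of the 8 deepest falls with the conjugate. These were -3.89 with an error of 0.47 for the spindle checkpoint kinase TTK, -3.78 with an error of 0.46 for the spindle gene DLGAP5, -3.77 with an error of 0.52 for the kinetochore gene NDC80 and -3.75 with an error of 0.40 for the flap endonuclease FEN1. Of 22 G2/M genes 19 fell and none rose (20 over the list alone), with a median of -1.46 (camera adjusted p = 1.54e-08; adjusted p = 0.479 with an estimated correlation). CCNB1 stood at -2.77 with an error of 0.32 and KIF20A at -2.38 with an error of 0.20. Of 27 G1/S and replication genes 20 fell (22 over the list alone), among them CDC25A (-1.97) and PCNA (-1.01), and MCM5 rose by 0.42 (list median -1.33, camera adjusted p = 9.99e-08; adjusted p = 0.479 with an estimated correlation). Of 16 DNA repair genes 12 fell (13 over the list alone), led by the mismatch repair gene MSH6 (-3.06 with an error of 0.30) and with BRCA1 at -1.21, and XRCC3 rose by 0.77 (list median -1.32, camera adjusted p = 2.95e-04; adjusted p = 0.479 with an estimated correlation). PCNA had 1 probe set, its most specific, that went to 0.38.

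The same arrays showed a shift of level that moved with these gene groups. The deposited values carry a per-probe-set baseline, and probe sets could be sorted by baseline level into 15568 dim, 23409 middle and 8949 bright ones. Between the conjugate and untreated arrays the median change was 0.50 for dim, 0.17 for middle and -1.11 for bright probe sets. Hybridization control transcripts, which are added in fixed amounts, lay 2.06 higher on the conjugate arrays (mean 1.68, SD 0.30) than on untreated arrays (mean -0.38, SD 0.05). Poly-A control transcripts lay 1.90 higher, background probe sets 0.52 higher, and 18S ribosomal RNA changed by -2.11. For each of these 4 the exact permutation p was 0.1, the lowest value that 3 against 3 arrays can give. After each array was centred within level classes, the median of the G2/M genes was -0.96 (camera adjusted p = 1.35e-04), that of the G1/S genes -0.59 (adjusted p = 1.35e-04), that of the DNA repair genes -0.47 (adjusted p = 0.0277) and that of the p53 targets -0.34 (adjusted p = 0.0175).

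**Figure D1:**
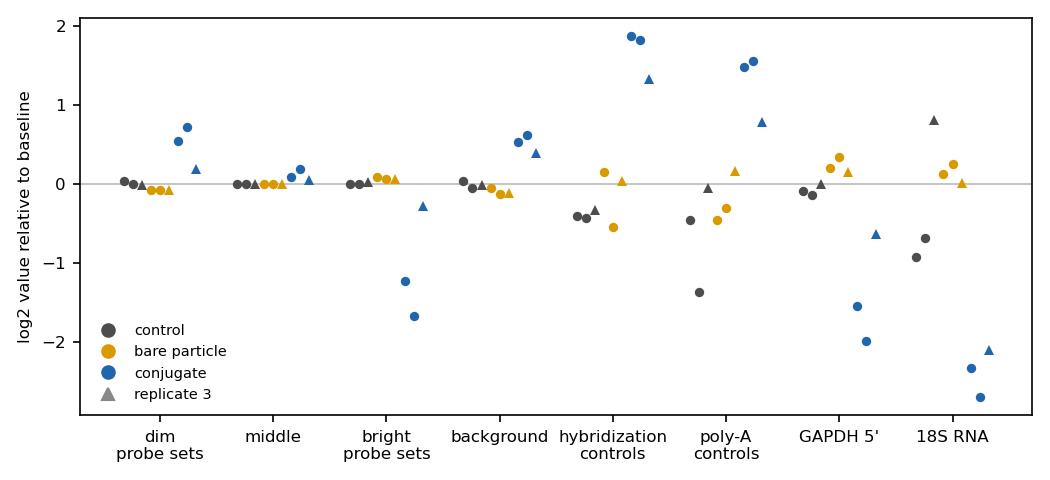
Median log2 value of dim, middle and bright probe sets and of control probe sets on each array. On conjugate replicate 2 the dim median was 0.72 and the bright median -1.67, and on conjugate replicate 3, drawn as a triangle, 0.19 and -0.28.

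Across all 49293 probe sets, 23985 passed limma at Benjamini-Hochberg adjusted p under 0.05, 12293 higher and 11692 lower, of which 14778 changed at least 2-fold. By level the split was 5132 higher and 92 lower among dim probe sets, 6203 and 5467 among middle ones, and 842 and 5230 among bright ones. With each array centred on its median the split was 8556 higher and 12653 lower, and after quantile normalization 1418 higher and 3822 lower. Without untreated replicate 3 it was 5584 higher and 8280 lower, and without conjugate replicate 3 it was 19697 and 14869. The median change of all probe sets was 0.23. By gene, 6006 of 18132 rose and 4560 fell.

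Genes of growth and energy supply fell as deposited, and no list of them stayed called lower after level centring. Of 19 ribosome biogenesis and MYC target genes 13 fell, over all genes and over the list alone, for example POLR1B (-2.28 with an error of 0.19) and RRS1 (-1.92 with an error of 0.27), which stayed called at -1.69 and -0.85 after level centring (limma adjusted p = 1.72e-04 and 0.023). Their median was -1.04 (camera adjusted p = 5.79e-06; adjusted p = 0.479 with an estimated correlation) and -0.32 after level centring (adjusted p = 0.132). Of 21 nuclear oxidative phosphorylation genes 14 fell by either adjustment, for example NDUFS1 (-1.96, and -1.13 with limma adjusted p = 0.00132 after level centring) and SDHC (-1.28). Their median was -0.87 (camera adjusted p = 1.25e-05; adjusted p = 0.479 with an estimated correlation) and 0.01 after level centring (adjusted p = 0.827). Of 25 ribosomal protein genes 14 fell by either adjustment, RPL19 (-0.86) and RPL6 (-0.78) among them (median -0.67, camera adjusted p = 1.16e-04; adjusted p = 0.479 with an estimated correlation). Level centring turned that list to 0.34 higher (adjusted p = 0.00503). Hypoxia and glycolysis genes had a median of -0.63 with 11 of 21 falling, such as P4HA1 at -1.52 (camera adjusted p = 0.00908; adjusted p = 0.479 with an estimated correlation), and 0.03 after centring.

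Falls called as deposited, but in no list after level centring, were also seen in stress, lipid and vesicle genes. Of 20 ATF4 and unfolded protein response genes 8 fell, such as HSPA5 (-1.80), and 2 rose, such as PPP1R15A (1.11) (list median -0.54, camera adjusted p = 0.0302; adjusted p = 0.479 with an estimated correlation). The NRF2 list had 7 of 16 falling, such as SRXN1 (-1.53), and 2 rising, HMOX1 by 2.47 with an error of 0.38 and the cystine transporter SLC7A11 by 0.92 (list median -0.54, camera adjusted p = 0.0437; adjusted p = 0.479 with an estimated correlation). Quantile normalization turned the median of the ATF4 list to 0.42 and that of the NRF2 list to 0.11. Cholesterol synthesis genes fell in 9 of 15 cases, such as SQLE (-1.77), and rose in 3 (median -0.99, camera adjusted p = 0.0321; adjusted p = 0.479 with an estimated correlation). Lysosome and autophagy genes fell in 12 of 23 cases, such as ATP6V1H (-1.64), and rose in 4, such as ULK1 (1.17), with a median of -0.50 (camera adjusted p = 0.0321; adjusted p = 0.479 with an estimated correlation). For these 4 lists the counts over the list alone were the same. Metal response genes rose in 5 of 11 cases, such as MT1F (1.41 with an error of 0.21), and fell in 1, SLC39A10 (-0.79), by either adjustment, with no camera call (median 0.48, adjusted p = 0.25; 0.53 after level centring) and a call by fry and after quantile normalization (adjusted p = 0.00825 and 0.00223). After level centring the medians were -0.03 for ATF4, 0.00 for NRF2, -0.12 for cholesterol and -0.10 for lysosome genes (camera adjusted p = 0.956, 0.508, 0.365 and 0.827). Endocytosis genes (8 fell and 5 rose of 20, or 8 and 6 over the list alone), pro-apoptotic genes (5 fell and 6 rose of 19) and anti-apoptotic genes (4 fell and 2 rose of 9, or 5 and 2) were not called by camera (adjusted p = 0.0693, 0.941 and 0.233). XIAP, a caspase inhibitor, fell by 1.16, and among pro-apoptotic genes HRK rose by 1.02 and CASP6 fell by 1.52.

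Some chaperone genes rose while others fell. DNAJB1 rose by 1.85 with an error of 0.32, HSPB1 by 1.55 with an error of 0.26 and the collagen chaperone SERPINH1 by 2.67 with an error of 0.45, and HSPA4L fell by 2.08. HSPA6, an inducible HSP70, rose by 3.47 with an error of 1.23 (limma adjusted p = 0.035). Without untreated replicate 3 its rise was 1.62, because this array lay at -6.37 and the other untreated arrays at -0.84 and -0.82. As a list, 5 of 13 heat shock genes rose and 3 fell (5 and 4 over the list alone), and camera made no call (median -0.07, adjusted p = 0.872). After level centring the median was 0.98 (adjusted p = 0.0175). Immediate early genes had 7 of 14 rising and none falling by either adjustment, FOS by 1.27 with an error of 0.20 and EGR3 by 0.92 (median 0.62, camera adjusted p = 0.0733; 0.59 and adjusted p = 0.0323 after level centring).

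Beside HSPA6, SERPINH1 and HMOX1, the 8 largest rises held genes of varied function. ZNF566-AS1 rose by 4.86 with an error of 0.73, the calmodulin binding gene PCP4 by 3.03 with an error of 0.50, the long noncoding RNA LINC02447 by 7.98-fold, the glucuronosyltransferase UGT2B7 by 2.37 with an error of 0.31 and ZBTB7C-AS2 by 2.30 with an error of 0.45. At the other end PDCD7, a part of the minor spliceosome, fell by 4.40 with an error of 0.59, beside FSTL5 (-3.89 with an error of 0.65) and TMEM170B (-3.88 with an error of 0.43).

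Interferon, NF-kB, pigment epithelium and blood cell lists rose. Interferon response genes rose in 13 of 16 cases, IFIT3 by 1.18 and OAS1 by 0.98 (median 0.71, camera adjusted p = 0.00556; adjusted p = 0.479 with an estimated correlation). Of 15 NF-kB genes 11 rose and 1 fell (12 and 2 over the list alone), the chemokine CXCL2 at 2.10 with an error of 0.37 and the inhibitor NFKBIA at -1.89 with an error of 0.35 (median 0.76, camera adjusted p = 0.0323; adjusted p = 0.479 with an estimated correlation). Retinal pigment epithelium markers rose in 7 of 9 cases (8 over the list alone), RPE65 by 0.68 (median 0.65, camera adjusted p = 0.0297; adjusted p = 0.479 with an estimated correlation). Blood cell markers rose in 8 of 11 cases, CD3D by 0.64 (median 0.64, camera adjusted p = 0.0209; adjusted p = 0.479 with an estimated correlation). Beside these, 167 of 333 olfactory receptor genes, a family picked after the data were seen, rose and none fell, with a median of 0.68 (0.34 after level centring). After level centring the interferon list stayed called (0.41, camera adjusted p = 0.0277), and the NF-kB (0.38), pigment epithelium (0.36) and blood cell lists (0.34) did not (adjusted p = 0.134, 0.134 and 0.227). Among 2000 random lists matched for level, the medians lay at percentile 99.4 for interferon, 99.6 for NF-kB, 87 for pigment epithelium and 93.8 for blood cell genes.

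Retinoblastoma genes fell as deposited, and level centring ended the call (median -0.27, camera adjusted p = 0.0799). RBP3, a photoreceptor matrix gene, fell by 3.95 with an error of 0.50, and IMPG2, of the same matrix, stood at -2.32 with an error of 0.21. Of 25 photoreceptor markers 6 fell and none rose (5 over the list alone), and camera made no call (median -0.26, adjusted p = 0.0841; 0.00 after level centring). Camera called the photoreceptor list lower in 3 of 22 alternatives, among them untreated replicate 3 alone (-0.71, adjusted p = 0.00597). Of 17 retinoblastoma genes 8 fell, such as RB1 (-0.98 with an error of 0.15) and the oncogene E2F3 (-1.73 with an error of 0.20), and 2 rose, such as NGFR (0.85), by either adjustment (list median -0.75, camera adjusted p = 0.0137; adjusted p = 0.479 with an estimated correlation). Of 13 microRNA processing genes 9 fell, such as DROSHA (-2.25 with an error of 0.45), and TARBP2 rose by 0.67 (1 rose, or 2 over the list alone; median -1.06, camera adjusted p = 0.0137; adjusted p = 0.479 with an estimated correlation). Of 11 retinal progenitor markers 5 rose, such as SIX6 (1.06), and 3 fell, such as SFRP2 (-2.10). Of 10 Mueller glia markers 2 rose and 2 fell, such as VIM (-2.14), and of 16 inner retinal neuron markers 9 rose and 4 fell, such as POU4F2 (-1.57). Fibroblast markers rose in 4 of 12 cases (3 over the list alone), PDGFRB by 1.05. Camera called none of these last 4 lists (adjusted p = 0.769, 0.762, 0.348 and 0.0693).

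**Figure D2:**
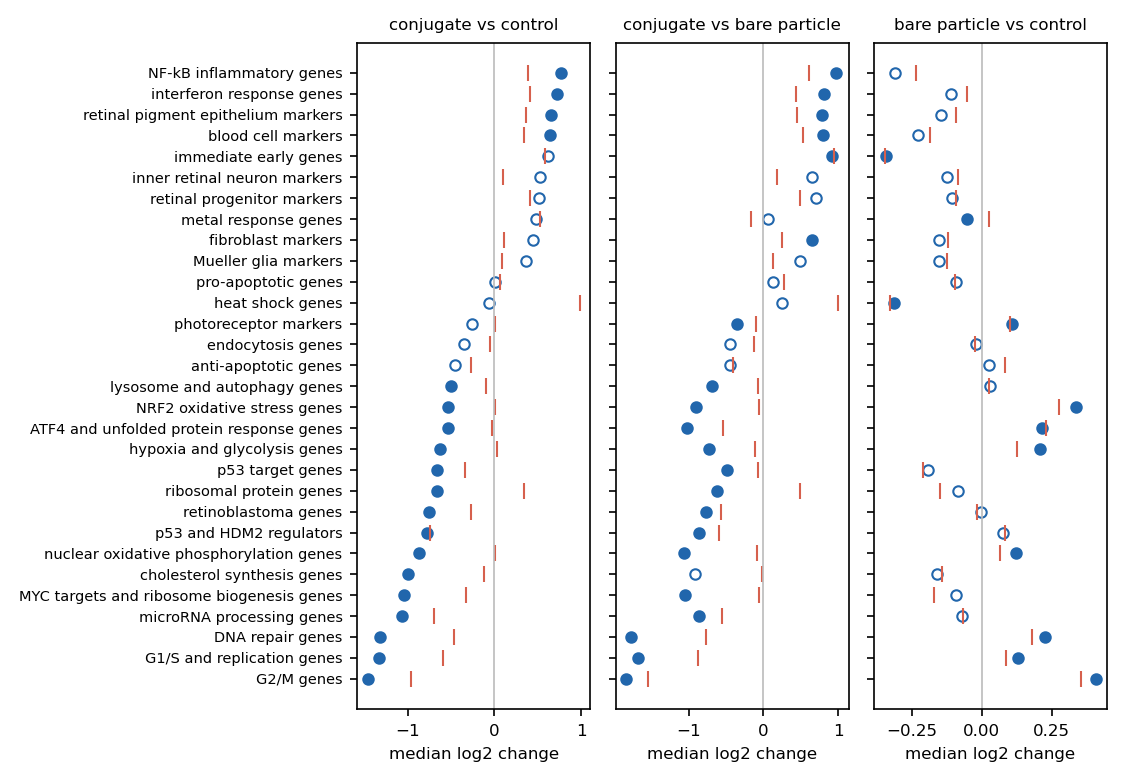
Median log2 change of each gene list in the 3 comparisons. Filled circles mark lists with camera adjusted p under 0.05, 19 of 30, 21 of 30 and 11 of 30 from left to right, and red ticks mark the median after centring within level classes.

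In all, camera called 19 of 30 lists against untreated cells, 4 higher and 15 lower, and none with an estimated correlation, where the lowest adjusted p was 0.479. The rotation test fry called 21. After level centring camera called 10, lower for p53 targets, regulators of p53 and HDM2, G2/M, G1/S, DNA repair and microRNA processing genes, and higher for heat shock, immediate early, interferon and ribosomal protein genes. Of the genes named above, MCM5 (0.30), SRXN1 (-0.46), SDHC (-0.38), P4HA1 (-0.45), RPE65 (0.38), RPL19 and RPL6 lost their limma call with that centring. Against 2000 random lists matched for level, 11 of 30 medians lay outside the central 95%. They were G1/S (percentile 0.2), G2/M (0.35), DNA repair (0.55), microRNA processing (1.65), retinoblastoma (1.9) and cholesterol genes (2.15) at the low end, and retinal progenitor (98.4), heat shock (98.6), immediate early (99.2), interferon and NF-kB genes at the high end. The p53 targets (2.55) and the regulators of p53 and HDM2 (6.05) lay inside.

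With bare gold particles, 4 genes rose against untreated cells, of which 2 were on the metal response list and 1 on the NRF2 list. The metallothionein MT1X rose by 3.39 with an error of 0.36, which is 10.5-fold (n = 3 arrays per group; limma adjusted p = 0.0169). PIR, an iron-binding protein gene on none of the lists, rose by 2.90 with an error of 0.19 (7.49-fold, adjusted p = 6.47e-04). The metallothionein MT1F rose 5.66-fold with a log2 error of 0.21 (adjusted p = 0.00326). The cystine transporter SLC7A11 rose by 1.71 with an error of 0.19 (3.27-fold, adjusted p = 0.0233), and its probe sets ranged from -0.14 to 3.03. After level centring it stood at 1.59 with no call (adjusted p = 0.267). MT1X and MT1F are close paralogs, and MT1F values came from 1 probe set at 3.98 and another at 1.02, so the share of each gene in these rises is uncertain. None of 18 probe sets of other MT1 and MT2A genes was at least 2-fold higher (range -0.31 to 0.41). These 4 rises were close to the baseline in the treated arrays (means 0.10 to 0.30) and below it in untreated arrays (means -3.08 to -1.49).

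By probe set the count was also 4, all higher, while 2286 of 49293 had unadjusted p under 0.05, and the median change of all probe sets was -0.04. After quantile normalization 5179 probe sets passed, 2356 higher and 2823 lower. That step widens the values of untreated and bare particle arrays to a spread shared with the conjugate arrays, so this is not a like count. The spread came from all 9 arrays, and the wide spread of the conjugate arrays entered the limma test. With only the 2 groups compared, 22 probe sets passed (20 higher and 2 lower), and by gene 57 rose and 4 fell. The rises in that fit included the quinone reductase NQO1 (2.29 with an error of 0.25), the cystathionine lyase CTH (2.10 with an error of 0.29), the ATF4 targets DDIT4 (1.66 with an error of 0.13), INHBE (1.64 with an error of 0.14) and ASNS (1.26 with an error of 0.16), and the zinc exporter SLC30A1 (1.15 with an error of 0.17). The falls were FOS (-1.13 with an error of 0.11), the transferrin receptor TFRC (-0.84 with an error of 0.12), PLEK2 and HAPLN4. With trend and robust settings in limma no probe set passed and 2516 had unadjusted p under 0.05.

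**Figure D3:**
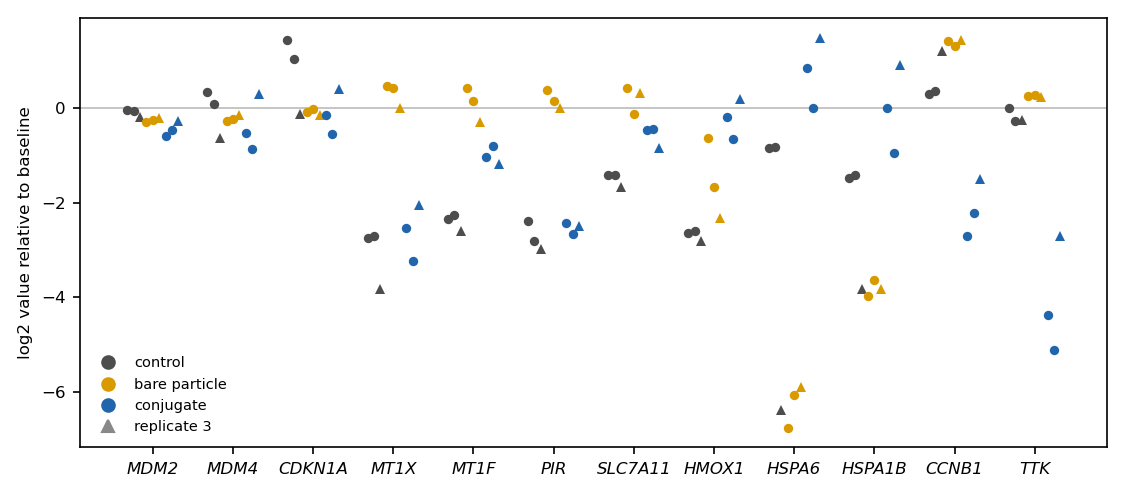
Values of 12 genes on each array. PIR lay between -2.98 and -2.38 on untreated arrays, between 0 and 0.40 on bare particle arrays and between -2.65 and -2.42 on conjugate arrays, and the triangle of each group marks replicate 3.

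As lists, NRF2 genes had a median change of 0.34 with bare particles (camera adjusted p = 2.13e-08; adjusted p = 0.378 with an estimated correlation), with 1 of 16 rising over all genes and 5 over the list alone. ATF4 and unfolded protein response genes had a median of 0.22 (adjusted p = 6.64e-05; adjusted p = 0.686 with an estimated correlation), with 0 of 20 over all genes by limma, 5 over the list alone and 4 by gene in the fit of the 2 groups. Metal response genes were called higher (adjusted p = 0.00567; adjusted p = 0.238 with an estimated correlation) on 2 of 11 genes, 3 over the list alone, while their median was -0.05. Against untreated replicate 3 alone, these 3 lists stayed called at medians of 0.22, 0.56 and 0.02 (camera adjusted p = 8.07e-09, 1.20e-15 and 2.52e-06, but 0.49, 0.329 and 0.17 with an estimated correlation). In that fit the spread came from the bare particle and conjugate arrays, and the lone untreated array was assumed to vary like them. MT1X was then 4.12, PIR 3.17 and MT1F 2.70 higher with no call left by limma (adjusted p = 0.228, 0.0586 and 0.317).

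G2/M genes had a median change of 0.41 (camera adjusted p = 8.40e-09; adjusted p = 0.686 with an estimated correlation) and stayed called against untreated replicate 3 alone at 0.16 (adjusted p = 0.0213; adjusted p = 0.921 with an estimated correlation). Immediate early genes had a median of -0.34 (camera adjusted p = 0.00156; adjusted p = 0.238 with an estimated correlation) and stayed called at -0.10 (adjusted p = 0.013; adjusted p = 0.329 with an estimated correlation). Other list calls ended against untreated replicate 3 alone. These were heat shock genes (-0.31 and adjusted p = 0.00493, then -0.04 and 0.2), hypoxia and glycolysis genes (0.21 and 0.0015, then 0.01 and 0.616), G1/S genes (0.13 and 0.00259, then 0.02 and 0.429), DNA repair genes (0.23 and 0.00872, then 0.21 and 0.142) and oxidative phosphorylation genes (0.12 and 0.0431, then 0.02 and 0.46). The photoreceptor list went from 0.11 (adjusted p = 0.0197) to -0.07. With an estimated correlation these 6 had adjusted p of 0.686, 0.686, 0.712, 0.712, 0.806 and 0.686. In these 8 lists no gene passed limma over all genes, and over the list alone 1 heat shock and 1 immediate early gene fell. The rotation test called 1 of the 11 lists that camera called, the metal response.

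The p53 targets had a median of -0.19 with bare particles and no camera call (adjusted p = 0.115). They were called lower after level centring (-0.21, adjusted p = 0.0172) and called higher against untreated replicate 3 alone (0.14, adjusted p = 0.00463, and 0.921 with an estimated correlation), so that no direction holds. MDM2 changed by -0.16 with an error of 0.15, MDM4 by -0.15 with an error of 0.32 and CDKN1A by -0.87 with an error of 0.37 (limma adjusted p = 0.877, 0.932 and 0.864). As deposited, camera called no shift in regulators of p53 and HDM2 (median 0.08), pro-apoptotic (-0.09), anti-apoptotic (0.03), lysosome (0.03), endocytosis (-0.02), cholesterol (-0.16), NF-kB (-0.31), interferon (-0.11), ribosome biogenesis (-0.09), ribosomal protein (-0.09), retinoblastoma (0.00) or microRNA processing genes (-0.07). NF-kB genes were called lower in 8 of 22 alternatives, and ribosomal protein genes only after level centring (-0.15, camera adjusted p = 1.48e-04). Ribosome biogenesis genes were called only against untreated replicate 3 alone (-0.24), and not there with an estimated correlation. The same held for markers of retinal progenitors (-0.11), Mueller glia (-0.15), inner retinal neurons (-0.12), pigment epithelium (-0.14), fibroblasts (-0.15) and blood cells (-0.23), of which the last 2 were each called in 1 of 22 alternatives.

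Untreated replicate 3 lay with the bare particle arrays for most genes that separated them from untreated replicates 1 and 2. Its mean correlation with the bare particle arrays was 0.547, against 0.021 with the other untreated arrays. With the conjugate arrays the mean correlation was 0.271 for untreated replicate 1, 0.177 for replicate 2 and -0.229 for replicate 3. Between untreated arrays r was 0.491 for replicates 1 and 2, 0.148 for 2 and 3 and -0.107 for 1 and 3. Whether replicate 3 or replicates 1 and 2 were displaced cannot be told from these arrays. Of 266 genes with limma p under 0.001 and at least 2-fold change between bare particles and replicates 1 and 2, 221 lay closer to the bare particle level on replicate 3. For HSPA6 replicate 3 stood at -6.37 and the bare particle mean at -6.24. None of the 8 members of the NRF2, metal and ATF4 lists among them lay closer to the bare particle level on replicate 3, where their positions ran from -0.538 for ASNS to 0.478 for GCLM. Of the 3 heat shock list members among them, HSPA1B and BAG3 lay at 1.008 and 1.221 and HSPH1 at 0.237 (median position 1.01).

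**Figure D4:**
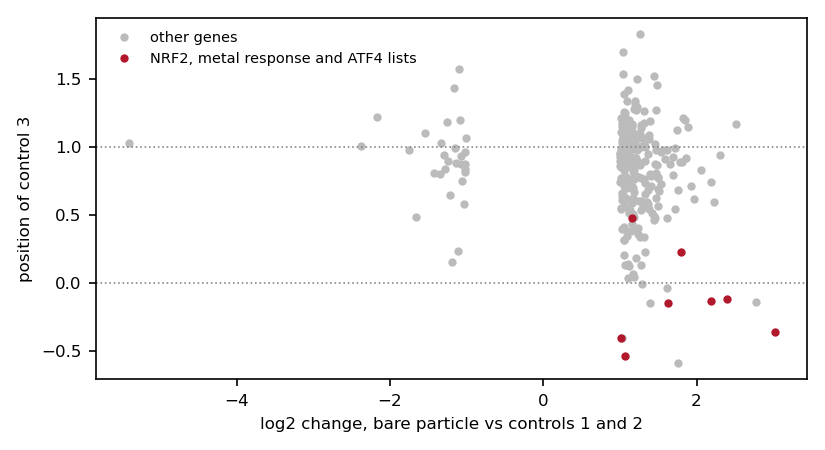
Position of untreated replicate 3 for 266 genes, with 0 at the mean of untreated replicates 1 and 2 and 1 at the bare particle mean. The median was 0.865 over all 266 genes and -0.144 over the 8 members of the NRF2, metal and ATF4 lists.

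Between conjugate and bare particles, single heat shock and cell cycle genes were among those furthest apart. HSPA6 was higher with the conjugate by 7.03 with an error of 1.23 (n = 3 arrays per group; limma adjusted p = 0.00149), HSPA1B by 3.80 with an error of 0.63, SERPINH1 by 3.85 with an error of 0.45 and the co-chaperone BAG3 by 3.14 with an error of 0.59. Untreated replicate 3 lay near the bare particle level for these genes (HSPA6 -6.37, HSPA1B -3.83, SERPINH1 -3.38 and BAG3 -3.21). Untreated replicates 1 and 2 lay higher (HSPA6 -0.84 and -0.82, HSPA1B -1.46 and -1.40, SERPINH1 -1.11 and -2.24, BAG3 -0.68 and -0.45). How much of these gaps belongs to either treatment is therefore not settled. The deepest falls were INHBE (-4.70 with an error of 0.26), NDC80 (-4.58 with an error of 0.52), TTK (-4.32 with an error of 0.47), DLGAP5 (-4.30 with an error of 0.46), the mitochondrial RNase LACTB2 (-4.23 with an error of 0.50) and DACH1, a retinal transcription cofactor (-4.22 with an error of 0.55). ZNF566-AS1 rose by 5.48, LINC02447 by 3.03, PCP4 by 2.97 and ZBTB7C-AS2 by 2.90, and PDCD7 and FSTL5 stood at -4.42 and -4.26.

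The metal genes raised by bare particles were lower with the conjugate than with bare particles, MT1X at -2.91 with an error of 0.36 and MT1F at -1.10 with an error of 0.21, and MT1G rose by 1.13 with an error of 0.19. After level centring MT1X stood at -1.56 (limma adjusted p = 0.00261) and MT1F at -0.59 with no call (adjusted p = 0.0821). MDM2 (-0.19 with an error of 0.15), MDM4 (-0.15 with an error of 0.32) and CDKN1A (-0.01 with an error of 0.37) did not pass limma (adjusted p = 0.256, 0.687 and 0.981). After level centring all 3 passed, CDKN1A at 1.12, MDM4 at 0.64 and MDM2 at -0.36 (limma adjusted p = 0.0181, 0.0377 and 0.0476). Of 30 p53 targets 12 fell and 3 rose, PHLDA3 by 1.01 and PLK3 by 0.81, with a median of -0.49 (camera adjusted p = 0.0082; adjusted p = 0.476 with an estimated correlation) and -0.08 after level centring (adjusted p = 0.215). Of the 11 probe sets of MDM2, 3 rose and 3 fell.

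By list, 21 of 30 were called by camera, 6 higher and 15 lower, none with an estimated correlation (lowest adjusted p = 0.476), 24 by fry and 7 after level centring. Those 7 were G2/M, G1/S, DNA repair and regulators of p53 and HDM2, all lower, and heat shock, immediate early and ribosomal protein genes, all higher. Against 2000 random lists matched for level, G1/S (percentile 0), G2/M (0.05) and DNA repair genes (0.1) lay below the central 95%, and interferon (98), heat shock (98.9), retinal progenitor (98.9), NF-kB (99.7) and immediate early genes (99.8) above it. The p53 targets (18) and regulators of p53 and HDM2 (10.2) lay inside. The median was -1.84 for G2/M genes (20 of 22 fell; camera adjusted p = 3.48e-09), with KIF20A at -3.16 and AURKA at -2.31. After level centring the list median was -1.55, KIF20A stood at -1.59 and AURKA at -0.74 with no call (limma adjusted p = 0.0864). It was -1.68 for G1/S genes (21 of 27 fell; adjusted p = 1.45e-07), with CCNE2 at -2.48, and -1.77 for DNA repair genes (13 of 16 fell; adjusted p = 1.71e-04), with MSH6 at -3.26. These 3 lists had the same counts over the list alone and adjusted p = 0.476 with an estimated correlation. NRF2 genes fell in 11 of 16 cases (median -0.90), such as GCLM (-2.28), and ATF4 genes in 15 of 20 (median -1.02), such as DDIT4 (-2.25), with camera adjusted p of 5.92e-04 and 0.00172, and adjusted p = 0.476 with an estimated correlation for both. Level centring ended both calls (-0.06 and -0.54, adjusted p = 0.438 and 0.149). Also called lower, with adjusted p = 0.476 with an estimated correlation, were regulators of p53 and HDM2 (median -0.86), oxidative phosphorylation (-1.06), ribosome biogenesis (-1.05), hypoxia (-0.73), lysosome (-0.69), retinoblastoma (-0.77), microRNA processing (-0.86) and photoreceptor genes (-0.35). Called higher were NF-kB (0.97) and interferon genes (0.81) and markers of pigment epithelium (0.79), blood cells (0.80) and fibroblasts (0.65), each likewise at adjusted p = 0.476 with an estimated correlation. Pro-apoptotic (0.13), anti-apoptotic (-0.44), metal response (0.06), endocytosis (-0.44) and cholesterol genes (-0.91) and markers of retinal progenitors (0.71), Mueller glia (0.50) and inner retinal neurons (0.66) were not called. Immediate early genes rose in 8 of 14 cases (median 0.91; camera adjusted p = 0.026; adjusted p = 0.476 with an estimated correlation), FOS by 2.41 and ZFP36 by 1.31, with a median of 0.95 after level centring. Heat shock genes rose in 6 of 13 cases and fell in 2, with no camera call (median 0.24, adjusted p = 0.651), and were called higher after level centring (adjusted p = 0.007).

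Across probe sets 31867 passed limma, 17914 higher and 13953 lower. With each array centred on its median the split was 14040 higher and 15064 lower, and after quantile normalization 9940 and 11079. The median change of all probe sets was 0.29, with 0.61 for dim, 0.20 for middle and -1.25 for bright probe sets, and hybridization controls lay 1.80 higher on the conjugate arrays. Ribosomal protein genes (median -0.62, 9 of 25 fell, none over the list alone; camera adjusted p = 0.00303; adjusted p = 0.571 with an estimated correlation) turned to 0.49 higher after level centring.

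The changes with bare particles and with the conjugate, both taken against the same untreated arrays, ran in opposite directions (Pearson r = -0.41, covariance -0.14 over 49293 probe sets). In 100 simulated data sets with unchanged groups the shared untreated arrays alone gave a mean r of 0.374 (95% of values from -0.068 to 0.915) and a mean covariance of 0.0241. With separate untreated arrays for the 2 changes r ranged from -0.56 to -0.163, and against untreated replicate 3 alone it was -0.037. MT1F and SLC7A11 rose in both comparisons against untreated cells, and by probe set 2 were higher in both. Independent lists would give 0.998, but these lists share their untreated arrays, so the count does not show an overlap beyond chance.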

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

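The tests of RNA amount, degradation, level, labels, shared handling, cross-hybridization and particle response in this part were chosen only after the results were seen, and the counts over other splits of the arrays were planned.

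Control probe sets, which enter none of the comparisons, stood out where every array of a treated group lay above every untreated array. Between conjugate and untreated arrays the difference was 2.06 for the hybridization controls together, 3.03 for the least concentrated of them (bioB) and 0.69 for the most concentrated (cre), and 1.90 for the poly-A controls. It was 0.52 for background probe sets and 0.65 for 28S ribosomal RNA. Between bare particle and untreated arrays it was 0.20 for the 3' probe set of GAPDH and 0.31 for the 5' probe set. Other control probe sets lay below all untreated arrays on the conjugate arrays, namely 18S ribosomal RNA (-2.11) and the 3' (-0.81) and 5' (-1.31) probe sets of GAPDH, and the hybridization controls of bare particle arrays overlapped those of untreated arrays.

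The first pattern weighed is that bright probe sets were lower and dim ones higher on the conjugate arrays. A shift set by level alone was tested as the whole cause of the fall of G2/M genes. Their median of -1.34 over 20 classed genes lay at percentile 0.57 of 10000 random gene lists of the same level classes (95% of them from -1.18 to -0.01). This argues against a shift that is the same for all genes of a class. A shift that depends on level within a class stays open, since olfactory receptor genes kept a median of 0.34 after level centring (camera adjusted p = 2.5e-04). Random lists also carry none of the correlation among G2/M genes, whose fall had camera adjusted p = 0.479 with an estimated correlation. Less cellular RNA relative to the added transcripts may have caused the shift, since the hybridization controls lay 2.06 higher, and the arrays do not say whether fewer cells, a lower yield or a loading difference lay behind it. RNA degradation cannot be told apart from the other causes, because the 5' minus 3' difference lay below all untreated arrays on every conjugate array for 1 of 2 transcripts, GAPDH (mean -0.54, SD 0.13, against -0.04, SD 0.04), while untreated values of actin ranged from -0.48 to 0.00. A biological cause, such as death of treated cells, was not tested.

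The second pattern is that untreated replicate 3 lay with the bare particle arrays. A mislabelled bare particle array was argued against by the 8 members of the NRF2, metal and ATF4 lists that differed. The median position of replicate 3 was -0.144 (quartiles -0.373 and -0.034) on a scale with untreated replicates 1 and 2 at 0 and bare particles at 1. These 3 lists were picked after their rise against all 3 untreated arrays was seen, which favours a low position on replicate 3. Of 3 heat shock list members, HSPA1B and BAG3 lay at 1.008 and 1.221 and HSPH1 at 0.237 (median 1.01). A difference in handling or culture that it shares with the bare particle arrays is a candidate explanation. The median position of 0.865 over 266 genes (quartiles 0.612 and 1.03) restates the pattern, so it cannot tell this candidate from other causes. The same measure gave 0.023 over 28 genes for replicate 1 and 0.086 over 30 genes for replicate 2. Those genes were picked anew with replicate 3 among the reference arrays, so the 3 values are not a like comparison. Replicates 1 and 2 may instead be the displaced arrays, since their mean correlation with the conjugate arrays was 0.271 and 0.177, against -0.229 for replicate 3. This was not tested. No biological explanation was tested, since the design names none for a single untreated array.

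The third pattern is the rise of metallothionein, NRF2 and ATF4 genes on the bare particle arrays. The difference that sets untreated replicate 3 apart was argued against as the cause for 8 list members, since that array did not share their rise. Their median position on it was -0.144, and 0 of 8 lay past the midpoint to the bare particle level, with GCLM closest at 0.478. The weight of this is limited, because the lists were picked after their rise against all 3 untreated arrays was seen, which favours a low position. Cross-hybridization within the metallothionein family cannot be told apart from a rise of each gene: 0 of 18 other MT1 and MT2A probe sets were at least 2-fold higher, but the probe sequences of MT1X and MT1F were not compared. A response to the gold particle itself stays open as well, because the 57 genes that rose had a median of 0.016 with the conjugate after level centring, with 16 higher and 17 lower (-0.59 as deposited, 4 higher and 23 lower), and the coating, any difference in dose and the level shift are not separated by the design. These genes were picked for a rise against the same untreated arrays, which favours a higher change with the conjugate. Against bare particles, as deposited, 51 of the 57 were lower and 0 higher (median -1.63), where the same picking favours a lower change.

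Of 10 splits of the 6 arrays of each comparison, which are too few for a share under 0.05, the real one gave 23985 probe sets between conjugate and untreated arrays, 4 between bare particle and untreated and 31867 between conjugate and bare particle arrays, and the highest other count by limma was 0 in each, so that 1 split reached the real count. At unadjusted p under 0.05 the other splits had at most 12616, 1129 and 5561 probe sets. Each other split mixes both groups on both sides, so a difference between the groups enters its spread and counts of 0 are likely beforehand. It also keeps part of that difference, since 2 arrays of a group stand against 1. The other splits therefore do not show what unchanged groups would give. For gene lists the real splits gave 19, 11 and 21 and the highest others 20, 9 and 22, with 3, 1 and 3 splits as large as the real one. The other split that gave 20 lists set untreated replicates 1 and 3 and conjugate replicate 3 against the rest, and the one that gave 22 set conjugate replicates 1 and 2 and bare particle replicate 3 against the rest. Both set conjugate replicate 3, which had the smaller shift, apart from conjugate replicates 1 and 2. Whether that shift gave these counts was not tested.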

How the results depend on the processing

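Centring within level classes, leaving out dim probe sets, replicate 3 alone for conjugate or untreated cells, gene means and the most specific probe set were chosen after seeing the data. Of those chosen beforehand, the filter on probe sets of lowest mean and the probe set of highest mean were not run, since the values have no level, nor the pseudocount, which was for linear values. The mean of the probe sets became the choice reported. Signal over background could not be computed for the same reason. Quantile normalization gave all arrays the same spread, which widened bare particle and untreated values and narrowed conjugate ones. Counts after it are therefore not like the others. Where no reason is given, the cause was not tested.

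Between conjugate and untreated cells, 23985 probe sets became 5240 after quantile normalization, 13358 with only the 2 groups in the fit, 43368 with array weights, which did not reach their convergence tolerance, 12056 with conjugate replicate 3 alone and 3868 with untreated replicate 3 alone. By stricter thresholds the counts were 14778 at 2-fold or more and 10241 at adjusted p under 0.01, and with fewer units tested 10566 as gene means. Leaving out 1 array gave 13864 (without untreated replicate 3) to 34566 (without conjugate replicate 3), with 15256 without untreated replicate 2 and 15825 without conjugate replicate 1. The 19 lists became 0 with an estimated correlation, 10 after level centring, 11 with conjugate replicate 3 alone and 8 with the most specific probe set, and 16 to 20 with 1 array left out.

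Between bare particles and untreated cells, 4 probe sets became 5179 after quantile normalization, 17424 with array weights, 22 with only the 2 groups, 22 with conjugate replicate 3 alone, which adds nothing to the estimate of spread, and 1 after level centring. Limma with trend and robust settings gave 0 (2516 at unadjusted p under 0.05) and with untreated replicate 3 alone 0 (367 at unadjusted p under 0.05). Leaving out 1 array gave 2 (without bare particle replicate 1 or 3) to 11 (without untreated replicate 3), and 10 without conjugate replicate 3. The 11 lists became 0 with an estimated correlation, 1 by fry and 7 with untreated replicate 3 alone (0 with an estimated correlation as well, also chosen after seeing the data), where the lone array is assumed to vary like the other groups, and 9 to 12 with 1 array left out.

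Between conjugate and bare particles, 31867 probe sets became 21019 after quantile normalization, 20461 at 2-fold or more, 19653 at adjusted p under 0.01, 20773 with conjugate replicate 3 alone and 13114 as gene means, and 24214 to 38223 with 1 array left out. The 21 lists became 0 with an estimated correlation, 7 after level centring, 13 with conjugate replicate 3 alone and 10 with the most specific probe set, and 20 to 21 with 1 array left out.

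The correlation of the 2 changes stayed negative under each alternative run. From -0.41 it went to -0.084 after quantile normalization, -0.455 by Spearman, -0.484 over called probe sets, -0.344 after level centring, -0.283 with conjugate replicate 3 alone and -0.037 with untreated replicate 3 alone. With separate untreated arrays it was -0.527, -0.327, -0.56, -0.163 and -0.197, and with 1 array left out -0.427 to -0.335.

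Some genes changed direction with the choice of probe set. In the most specific probe set, conjugate against untreated, BCL2L2 was -0.79, CREBBP 0.077, GCLC 0.78 and PCNA 0.38, and against bare particles BCL2L2 was -0.98, BIRC5 0.65, LIN28B 0.29, POLH 0.42 and PSAT1 0.37. Without dim probe sets BCL2L2 was -0.79 and CFLAR -0.019 against untreated cells, and BCL2L2 was -0.98, CFLAR -0.045 and NDRG1 -0.19 against bare particles. Probe sets of one gene that moved both ways past the threshold were seen in GCLC, MDM2 and THRB against untreated cells, and in BCL2L2, BIRC5, MDM2 and PFKFB3 against bare particles.

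Scaling turned others, by the direction camera gave for lists. After level centring RPL19 was 0.21, RPL6 0.29 and SLC1A3 -0.043 against untreated cells, and the medians were 0.34 for ribosomal protein genes, 0.004 for NRF2 oxidative stress genes and -0.032 for ATF4 and unfolded protein response genes. With that centring CDKN1A and MDM4, lower without a call as deposited, were 0.186 and 0.435 against untreated cells and 1.12 and 0.644 against bare particles. Against bare particles CNGB3 was -0.12, RPL19 0.29 and RPL6 0.41, and the ribosomal protein genes had a median of 0.49, and of 0.077 with conjugate replicate 3 alone. After quantile normalization the NRF2 oxidative stress genes had a median of 0.11 and the ATF4 and unfolded protein response genes of 0.42 against untreated cells. Bare particle photoreceptor markers had a median of -0.068 against untreated replicate 3 alone.

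With the replicate number as a replicate block the counts were 23704, 4 and 31017 probe sets and 19, 11 and 21 lists. The numbers do not pair the arrays: of 9 pairs with the same number, 2 had a residual correlation over 0.1 and 4 were best with their own number (-0.033 to 0.231).

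Of the genes and lists named, 238 kept direction and side of the threshold after quantile normalization and 76 lost the call, 303 and 16 after median centring, 251 and 51 after level centring, 266 and 52 with conjugate replicate 3 alone, 245 and 72 with untreated replicate 3 alone, 260 and 51 with the most specific probe set and 300 and 20 with only the 2 groups.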

Other observations

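The gene families, the olfactory receptor comparison and the p53 test in this part were chosen only after the results were seen.

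Gene families picked by symbol moved both ways with the conjugate, and most of their medians shrank when level was taken into account. Quantile normalization also narrows the conjugate values as a whole, so its smaller medians do not measure level alone. Splicing factor genes of the SRSF and HNRNP families fell in 22 of 34 cases and rose in none (median -1.24, camera adjusted p = 1.23e-07; 0.349 with an estimated correlation), with -0.48 after level centring and -0.37 after quantile normalization. Mitochondrial ribosomal protein genes fell in 45 of 71 cases and rose in 1 (median -1.04, -0.31 after level centring and -0.38 after quantile normalization). Proteasome subunit genes fell in 26 of 35 cases (median -1.05), with -0.12 after level centring, and chaperonin CCT genes in 7 of 9 (median -1.25, then -0.31). Histone genes rose in 33 of 71 cases and fell in 2 (median 0.50, 0.25 after level centring and 0.37 after quantile normalization), and keratin-associated protein genes in 47 of 82 (median 0.63, 0.36 and 0.21). Aminoacyl-tRNA synthetase genes had a median of -0.72, which quantile normalization turned to 0.03, and serine and one-carbon enzyme genes one of -0.41, which it turned to 0.44 and level centring to 0.20.

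With bare particles serine and one-carbon enzyme genes had a median of 0.49 over 9 genes (camera adjusted p = 1.30e-07; 0.166 with an estimated correlation) and aminoacyl-tRNA synthetase genes 0.38 over 17 (adjusted p = 1.77e-05; 0.497 with an estimated correlation), while no single member passed limma over all 9 arrays. With only the 2 groups in the fit, CTH, PSAT1, PSPH, PHGDH and the synthetase gene CARS1 passed. Both kept the direction after level centring (0.42 and 0.32) and against untreated replicate 3 alone (0.62 and 0.25). After quantile normalization, which widens these differences, they stood at 0.92 and 0.78. Many genes of these 2 families are targets of ATF4. Between conjugate and bare particles their medians were -1.17 and -1.19 (camera adjusted p = 0.306 for both with an estimated correlation). After level centring they were -0.82 and -0.42, where the first was no longer called (camera adjusted p = 0.11 and 0.0241). Mitochondrial ribosomal protein genes had a median of 0.18 with bare particles, and of 0.05 against untreated replicate 3 alone.

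Signal gained by probe sets of silent genes may account for the rise of the interferon, NF-kB, blood cell and retinal pigment epithelium lists with the conjugate. Against 10000 random lists of olfactory receptor genes of the same size, their medians lay at percentiles 62.7, 76.3, 37 and 39.1, so that none rose beyond what olfactory receptor genes did (median 0.68). Interferon and NF-kB genes lay at percentiles 99.4 and 99.6 of random lists matched for level. Over 22 alternatives, most of which keep the level shift, the interferon list was called in 20 (camera or fry adjusted p from 0.00172 to 0.479). It also stayed called after level centring (0.41, camera adjusted p = 0.0277). Olfactory receptor genes (0.34, camera adjusted p = 2.5e-04) and keratin-associated protein genes (0.36, adjusted p = 0.0012) stayed called after that centring as well. A call that outlasts level centring therefore does not set the interferon list apart from these families. A true rise of these genes stays open.

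That p53 freed by the conjugate raises its target genes as a set was put to the level-centred values, where 30 p53 targets had a median of -0.344, the opposite of what such a rise needs (camera adjusted p = 0.0175). Over 22 alternatives, of which level centring was 1, the list was called in 20, with medians from -1.11 to -0.24 (camera or fry adjusted p from 6.05e-07 to 0.479). Most of the others keep the level shift, so they do not test the level-centred value. Against bare particles the level-centred median was -0.08 with no call, and among random lists matched for level the p53 targets lay at percentiles 2.55 against untreated cells and 18 against bare particles, so the ways of taking level into account differ on whether the targets fell beyond it. As deposited, 12 of 30 targets fell in each comparison, while 1 rose against untreated cells, PHLDA3, and 3 rose against bare particles. After level centring CDKN1A was called higher against bare particles (1.12, limma adjusted p = 0.0181) and stood at 0.186 against untreated cells. A rise at another time may have been missed, since the labels give no time of treatment, and protein was not measured.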
